A study of Homo sapiens with 8 samples.

How the data were processed

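Mature miRNAs were measured in Jurkat cells, a human T cell leukaemia line, on 8 one-colour arrays that share 1 chip. Per the labels' protocols, total RNA was extracted with phenol and chloroform, and labelled with biotin by a mirVana labelling kit. Treated cultures received 8 µM camptothecin for 4 hours, and treated and untreated cultures were separated by magnetic sorting into apoptotic and non-apoptotic fractions. Samples with higher RNA integrity were chosen for the arrays, per the series' design text. By the same text, the untreated apoptotic fraction had too few cells and was left out by the authors. The scanner, its software and the array maker were not given in the sources used here.

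The authors deposited a table of raw spot intensity, with the background intensity of the sector around each spot, and a matrix of processed intensity per miRNA. Both are on a linear scale and neither is normalized between arrays. Per the file headers, the spot table gives 6062 spots per array, which are 866 human entries with 7 spots each, in 14 sectors. The deposited matrix was compared with the spot table: each of its 6928 values equalled the mean over 7 spots of signal minus sector background within 0.001, or 10 where that mean was 0 or lower. That floor applies to 5830 of the values, so the median of every matrix column is 10. The matrix therefore has a linear scale, no centring and no ratio direction, and only its software stays unknown. Neither table holds blank or control spots, so all 866 entries were tested, as planned for that case.

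Spot signals were corrected with limma's normexp against the sector background with an offset of 50. The log2 values were summarised as the median of the 7 spots and quantile-normalized between arrays (limma 3.58.1, R 4.3.3). Linear models with 1 mean per group were fitted to all 8 arrays with lmFit and eBayes, without a replicate term. Two-sided p-values were adjusted by Benjamini-Hochberg over the 866 entries of a comparison, and an adjusted p under 0.05 was the threshold. Every adjusted p below is limma's unless camera is named. Fold changes are on the scale of the offset intensities, so those of dim entries are understated. An entry counted as above background on an array where all 7 of its spots exceeded their sector background. Where an entry was above background on no array of a group, only a bound or no value is given. It sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the entry's own value and the lowest value among entries above background.

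There were 3 comparisons of groups, and 18 lists of miRNAs fixed before the data were examined were tested in each with limma's camera at a preset correlation of 0.01. Its p-values were adjusted over the 54 tests, and the tests were repeated with an estimated correlation. The lists were the miR-17~92 and paralog clusters, the let-7, miR-15/16 and miR-181 families, p53-responsive, anti-apoptotic or oncogenic, pro-apoptotic or tumour-suppressive, T-ALL oncogenic, T cell and haematopoietic, DNA damage response, and hypoxia and stress miRNAs. The others were entries later recognised as fragments of other RNAs, GC-rich entries, markers of other cell types, pluripotency clusters, the C19MC and C14MC clusters, and star strands. A list needed at least 3 measured members. The lists overlap, and not every shared member is given here: miR-19b, miR-20a and miR-92a are in the miR-17~92, anti-apoptotic and T-ALL lists. miR-17 and miR-19a are in the miR-17~92 and anti-apoptotic lists. The DNA damage list shares miR-18a and miR-106b with miR-17~92, and miR-15a and miR-16 with miR-15/16. It also shares miR-182 with the anti-apoptotic list and miR-181a with the miR-181 family. The miR-15/16 and pro-apoptotic lists share miR-15a, miR-16 and miR-195, and the T-ALL and pro-apoptotic lists share miR-26a. The T cell list holds the miR-181 family. Calls of lists that share members are not independent results.

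Named miRNAs follow a rule fixed before the data were examined. It takes, per comparison, up to 12 entries in each direction that passed the threshold with no overlap between the groups' arrays. Where fewer than 5 passed, it adds the 10 with the smallest p. It also takes the 2 brightest members of each list, the 2 largest changes of each list past its threshold, the 10 brightest entries and 10 miRNAs fixed by name: miR-21, miR-155, miR-34a, miR-16, miR-17, miR-19b, miR-181a, miR-142-3p, let-7a and miR-223. Names are those of the array's design, and 844 of the 866 match a miRNA gene or synonym of RefSeq on GRCh38.p14. The 22 unmatched entries include all 11 measured members of the fragment list.

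The scripts were tested on simulated arrays with the real levels and spread. In 20 draws of 866 entries per comparison, with 40 changed, a log2 change of 1 was recovered in 87.2% of cases for JAP against JAN, 78.5% for JAP against JNN and 82% for JAN against JNN. False calls were 4.71%, 5.07% and 5.45% of all calls. When the simulated arrays were quantile-normalized again after the changes, recovery was 74.8%, 67.2% and 69.8% and false calls were 10.3%, 9.62% and 9.56%, in the same order. Camera found 20 of 20 simulated lists of 10 entries shifted by 1 in each comparison. It also called 0 of 20 unshifted lists for JAP against JAN, and 1 of 20 in each of the other comparisons.

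The alternatives were no background correction, an offset of 16, cyclic loess, scaling to the 75th percentile, no scaling, the mean of spots, the deposited matrix and only the entries brighter than the median entry. Others were eBayes with trend and robust settings, array weights, fits of the compared groups alone, the replicate number as a block, each array left out, other thresholds, and camera with an estimated correlation. A filter on entries above background on at least 2 arrays, the joint removal of JAP replicates 1 and 2, and the overlap with each array left out were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.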

Results

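Mature miRNAs were profiled in Jurkat T cell leukaemia cells sorted after exposure to camptothecin, a topoisomerase I inhibitor that breaks DNA and triggers apoptosis. The apoptotic fraction of treated cells (JAP) was measured on 3 arrays, the non-apoptotic fraction of treated cells (JAN) on 3, and the non-apoptotic fraction of untreated cells (JNN) on 2. The JNN arrays hold 3 replicates mixed into 2 samples. The labels do not say how they were mixed, so whether the JNN samples share material, and with it what their SDs and the p-values against JNN measure, is not known. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. The 8 arrays lie side by side on 1 chip with each group in its own stretch, so chip position and group cannot be told apart.

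The number of the 866 entries above background was 65, 49 and 100 on JAP replicates 1, 2 and 3. It was 131, 97 and 110 on the JAN arrays, and 87 and 93 on the JNN arrays. Of the entries, 44 were above background on all 8 arrays and 727 on none. The median coefficient of variation over the 7 spots of entries above background ran from 26.5% (JAN replicate 3) to 44.7% (JAP replicate 1). The number of arrays limits the precision. Members of a miRNA family differ by few bases, and cross-hybridisation between their probes was not measured.

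The 10 brightest entries were miR-1826, miR-494, miR-923, miR-149*, miR-638, miR-1308, let-7d, miR-16, miR-106a and let-7a. Among them, miR-1826 and miR-923 are ribosomal RNA sequences and miR-1308 is a tRNA fragment in later annotation. The normalized log2 intensity of miR-1826 was 14.32 ± 0.14 (SD, n = 3) in JAP, 14.40 ± 0 in JAN (n = 3) and 14.40 ± 0 in JNN (n = 2). An SD of 0 arises where quantile normalization gives entries of equal rank the same value. For let-7a, a tumour-suppressive family member, the values were 11.16 ± 0.73, 11.98 ± 0.08 and 11.74 ± 0.06. Those of miR-16, which targets the survival factor BCL2, were 10.69 ± 1.26, 12.46 ± 0.20 and 12.52 ± 0.25.

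The JAP arrays differed from each other. The deposited intensity of let-7a was 398 and 940 on JAP replicates 1 and 2, against 4973 on JAP replicate 3, 4679 to 6037 on the JAN arrays, and 2617 and 3122 on the JNN arrays. For miR-16 it was 161, 850 and 4466 on the JAP arrays, 6437 to 7674 on JAN, and 4877 and 4914 on JNN. For miR-17, of the oncogenic miR-17~92 cluster, it was 159, 353 and 2569 on JAP, 3939 to 5341 on JAN, and 3430 and 3449 on JNN. The first principal component held 59.5% of the variance and placed JAP replicates 1 and 2 at -11.4 and -8.15, JAP replicate 3 at 0.56, and the JAN and JNN arrays between 3.26 and 4.94.

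**Figure D1:**
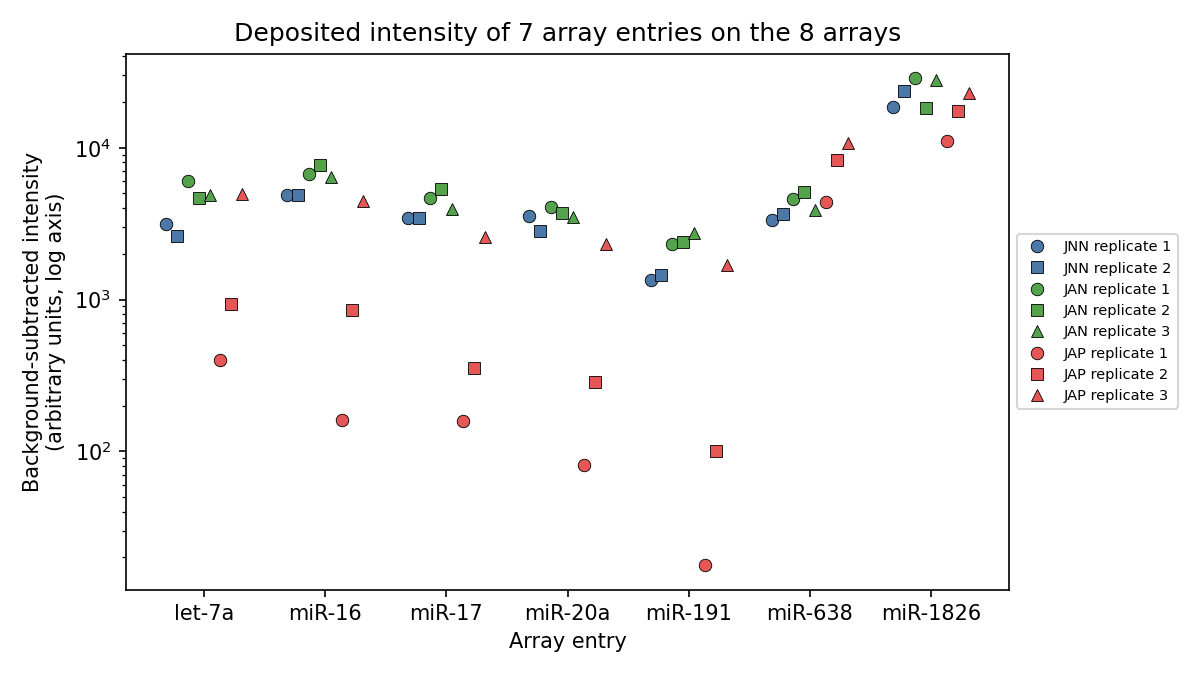
Deposited background-subtracted intensity (arbitrary units, log axis) of 7 array entries on the 8 arrays, with 1 point per array, colour for the group and shape for the replicate. For let-7a, miR-16, miR-17, miR-20a and miR-191, JAP replicates 1 and 2 lie below the other 6 arrays (81.7 and 287 for miR-20a against 2335 to 4102), whereas miR-638 reads 4402 or more on all JAP arrays.

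Treated cells that had entered apoptosis were compared with treated cells that had not (JAP against JAN). Members of the miR-17~92 cluster and its paralogs were lower in JAP. miR-17 fell 2.90-fold (log2 fold change -1.54, SE 0.21, adjusted p = 0.00718, limma), from 11.87 ± 0.16 (SD, n = 3) to 10.34 ± 0.50 (n = 3). miR-20b fell 3.00-fold (adjusted p = 0.048), miR-93 2.62-fold (0.0417) and miR-18a 2.78-fold (0.0453). Outside this cluster, miR-191 fell 3.17-fold (log2 -1.67, SE 0.36, adjusted p = 0.0431), miR-130b 3.02-fold (0.0298), miR-103 2.98-fold (0.0453) and miR-182 2.18-fold (0.048). Of the falls named so far, all but that of miR-17 belong to entries above background on only 1 of 3 JAP arrays. Their sizes rest largely on JAP values near background. The same limit holds for miR-15b, miR-181b, miR-26a, miR-19b and miR-107 below. Of 28 entries on the GC-rich list, which was set by entry name, 6 rose and 2 fell. The 2 that fell were miR-320 members. The largest rises were miR-663 at 2.90-fold (log2 1.53, SE 0.27, adjusted p = 0.0189) and miR-1228* at 2.87-fold (log2 1.52, SE 0.23, adjusted p = 0.00835).

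In all, 20 of 866 entries passed limma's threshold, 6 higher and 14 lower in JAP, and 159 had an unadjusted p under 0.05. The JAP and JAN arrays did not overlap for any of the 20, which their selection favours. Over all 866 entries, 184 (21.2%) did not overlap, where the chance share for 3 against 3 is 10%. Of the lower entries, miR-185, miR-425, miR-1244 and miR-340 were above background on no JAP array. The bounds for the first pair were small: miR-185 was at least 1.05-fold lower (adjusted p = 0.0295) and miR-425, the partner of miR-191 in 1 transcript, at least 1.02-fold lower (adjusted p = 0.0453). miR-1244 was above background on 1 JAN array and miR-340 on none, and neither gave a bound. miR-340 lies outside the naming rule and is given because it passed. Limma's count was 0 without JAP replicate 1 and 0 without JAP replicate 2 (116 and 115 at an unadjusted p under 0.05), and 114 without JAP replicate 3. It was 2, 7 and 1 without JAN replicates 1, 2 and 3, and 7 without either JNN array.

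**Figure D2:**
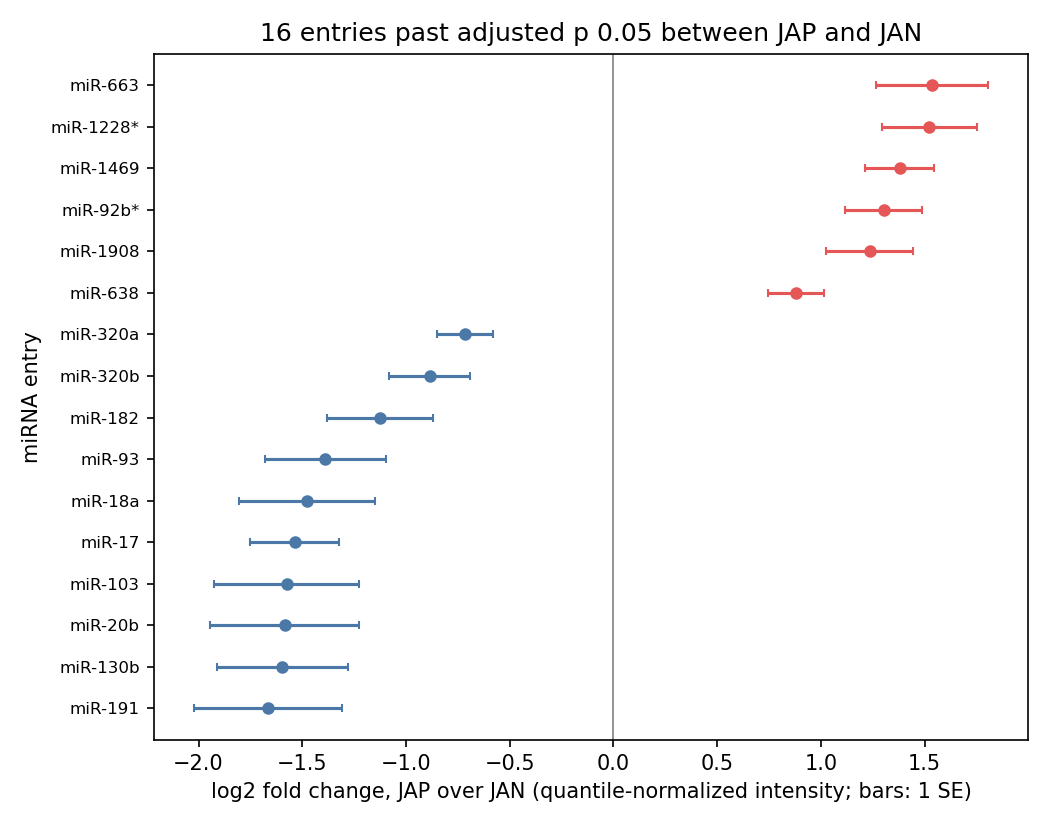
Log2 fold change of JAP over JAN from quantile-normalized intensity, with bars of 1 SE, for the 16 entries past the threshold that were above background on at least 1 array of each group (n = 3 per group). The 6 higher entries lie between 0.88 (miR-638) and 1.53 (miR-663), and the lowest is miR-191 at -1.67.

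Camera called 11 lists lower and 2 higher in this comparison. Several held few members above background on at least 2 arrays: 3 of 7 miR-15/16, 6 of 14 anti-apoptotic, 4 of 18 pro-apoptotic and 5 of 17 T cell entries. The counts of lower members given below for these lists exceed those numbers, so they include entries near background. For DNA damage response and hypoxia miRNAs the numbers were 6 of 14 and 3 of 10. Of the 13 members of the miR-17~92 and paralog clusters, 4 fell and 9 did not pass, with 13 lower when adjusted over the list alone. Their median log2 fold change was -1.32 (camera adjusted p = 8.08e-14, adjusted p = 0.32 with an estimated correlation). That median was -0.811 without background correction, -3.86 with the deposited matrix and -0.536 without JAP replicates 1 and 2. Of the 9 let-7 members, none passed over all entries and 8 were lower when adjusted over the list alone (median -0.82, camera adjusted p = 5.02e-06, and 0.381 with an estimated correlation). Their median was -0.529 without JAP replicate 1 and -0.103 without JAP replicates 1 and 2 (camera adjusted p = 0.437). On the normalized scale the list stood at -1.17, -0.886 and 0.0131 on JAP replicates 1, 2 and 3 against the mean of the JAN and JNN arrays. The largest values were let-7d at -1.33 (SE 0.36, adjusted p = 0.0786) and let-7f at -1.13 (SE 0.33, adjusted p = 0.0925). Of the 7 miR-15/16 members, 0 passed and 4 were lower when adjusted over the list alone (median -0.41, camera adjusted p = 0.00655, 0.381 estimated). miR-16 stood at -1.77 (SE 0.46, adjusted p = 0.0781) and miR-15b at -0.95 (SE 0.31, adjusted p = 0.132). Of the 4 miR-181 members, which set T cell receptor sensitivity, 0 passed and 3 were lower when adjusted over the list alone (median -0.73, camera adjusted p = 0.00447, 0.406 estimated), with miR-181b at -1.09 (SE 0.34, adjusted p = 0.112). Its 2 members above background on at least 2 arrays stood at -1.71 and -1.08 on JAP replicates 1 and 2 and at 0.0894 on JAP replicate 3, as medians on the same scale. The call was lost without JAP replicates 1 and 2 (median -0.115, camera adjusted p = 0.527), as were those of miR-15/16 (-0.215, 0.152), DNA damage response (-0.101, 0.152), hypoxia (-0.172, 0.27), p53-responsive (-0.075, 0.437) and C19MC entries (0.038, 0.665).

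Lists named for opposite roles in apoptosis were both lower in JAP. Of the 14 anti-apoptotic or oncogenic miRNAs, 2 fell (miR-17 and miR-182) and 12 did not pass, with 8 lower when adjusted over the list alone (median -0.66, camera adjusted p = 7.07e-06, 0.32 estimated). Of the 18 pro-apoptotic or tumour-suppressive miRNAs, only 4 were above background on at least 2 arrays. Among the 18, 0 passed and 9 were lower when adjusted over the list alone (median -0.35, camera adjusted p = 5.77e-05, 0.381 estimated). miR-26a, its brightest member after miR-16, stood at -1.25 (SE 0.33, adjusted p = 0.0781). Of 5 T-ALL oncogenic miRNAs, 0 passed, with 4 lower and 1 higher when adjusted over the list alone (median -1.29, camera adjusted p = 0.00558, 0.334 estimated). miR-19b stood at -1.32 (SE 0.33, adjusted p = 0.0711), and the higher one was the myeloid miR-223 at 0.54 (SE 0.18, adjusted p = 0.132). miR-223 is 1 of 2 markers of other cell types above background on at least 2 arrays. Against the mean of the JAN and JNN arrays, their median on JAP replicates 1 and 2 was 0.62 and 0.314 with quantile normalization. Without scaling it was -0.189 and 0.0357, so the higher value of miR-223 may depend on the scaling.

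Of 17 T cell and haematopoietic miRNAs, 2 fell (miR-191 and miR-425), and 9 were lower when adjusted over the list alone (median -0.46, camera adjusted p = 7.16e-06, 0.32 estimated). Of 14 DNA damage response miRNAs, 2 fell (miR-18a and miR-182), and 6 were lower when adjusted over the list alone (median -0.37, camera adjusted p = 0.000798, 0.406 estimated). Of 10 hypoxia and stress miRNAs, 0 passed and 2 were lower when adjusted over the list alone (median -0.38, camera adjusted p = 0.0265, 0.406 estimated). Its members miR-23b and miR-23a were above background on no JAP array, and neither gave a bound. Of 13 p53-responsive miRNAs, 0 passed and 1 was lower when adjusted over the list alone (median -0.12, camera adjusted p = 0.0265, 0.406 estimated). That call was also lost without JAP replicate 1 (adjusted p = 0.117), with 75th-percentile scaling (0.123), without scaling (0.0888), with the mean of spots (0.0627) and with the deposited matrix (0.975), all by camera. Jurkat cells lack wild-type p53. Only 1 of those 13, miR-107, was above background on 2 or more arrays, and it stood at -1.55 (SE 0.41, adjusted p = 0.0781). The p53 target miR-34a was above background on no array, as were miR-21, miR-155 and miR-142-3p.

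GC-rich entries rose as a list in JAP against JAN, but camera's direction turned down without scaling between arrays, with 75th-percentile scaling and with the deposited matrix. Of 28 entries, 6 rose, 2 fell and 20 did not pass, and adjusted over the list alone 13 were higher and 4 lower (median 0.31, camera adjusted p = 2.48e-05, 0.32 estimated). miR-1469 rose 2.60-fold (log2 1.38, SE 0.17, adjusted p = 0.00445), miR-92b* 2.47-fold (0.00718), miR-1908 2.36-fold (0.0161) and miR-638 1.84-fold (0.00835). Without scaling between arrays the list's median was 0.04 (camera adjusted p = 0.66), and the 6 entries lay between 0.38 (miR-1908) and 0.71 (miR-663), none past the threshold.

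Lists for tissues other than T cells had few measurable members. Only 1 of the 59 entries of the C19MC placental cluster was above background on at least 2 arrays. Its median was 0.12 with none past the threshold (0 when adjusted over the list alone, camera adjusted p = 0.0265, 0.499 estimated), and its brightest member miR-518b stood at 0.41 (SE 0.16, adjusted p = 0.204). The 34 markers of other cell types had a median of -0.001245 (camera adjusted p = 0.64), with miR-223 and miR-133b as the brightest. The 63 entries of the C14MC imprinted cluster had a median of 0.03 (0.908), with miR-494 at 0.08 (SE 0.12, adjusted p = 0.807) and miR-409-3p at 0.71 (SE 0.22, adjusted p = 0.112). Medians were 0.011 for 9 pluripotency entries (camera adjusted p = 0.815; brightest miR-371-5p and miR-302c), 0.049 for 174 star strands (0.308; miR-149* and miR-1228*) and -0.088 for 11 fragment entries (0.17; miR-1826 and miR-923). No member of these passed except 2 star strands, miR-1228* and miR-92b*.

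Treated apoptotic cells were then compared with untreated non-apoptotic cells (JAP against JNN). miR-17 fell 3.22-fold (log2 -1.69, SE 0.24, adjusted p = 0.0101, limma), from 12.02 ± 0.05 (SD, n = 2) to 10.34 ± 0.50 (n = 3). The GC-rich entries miR-663 and miR-1469 rose 3.66-fold (log2 1.87, SE 0.30, adjusted p = 0.0213) and 2.55-fold (log2 1.35, SE 0.19, adjusted p = 0.0101). These 3 of 866 entries passed, with 96 at an unadjusted p under 0.05, and all 3 were among those called against JAN. The next smallest p-values, which did not pass, belonged to miR-638 at 0.78 (SE 0.15, adjusted p = 0.0714) and, each at an adjusted p of 0.0807, to miR-92b*, miR-20b, miR-1228*, miR-106a, miR-18a and miR-185. miR-20b stood at -1.82 (SE 0.40) and miR-106a at -1.83 (SE 0.41). Limma's count was 0 without JAP replicate 1, JAP replicate 2, JNN replicate 1 or JNN replicate 2 (72, 74, 51 and 60 at an unadjusted p under 0.05), and 85 without JAP replicate 3.

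Of the 13 miR-17~92 and paralog members, 1 fell against JNN and 12 did not pass, with 12 lower when adjusted over the list alone (median -1.34, camera adjusted p = 1.05e-15, and 0.32 with an estimated correlation). Camera also called 7 other lists lower, each losing the call with an estimated correlation. They were let-7 (median -0.51, adjusted p = 0.00115, 0.492 estimated), miR-15/16 (-0.35, 0.0102, 0.381), anti-apoptotic (-0.56, 6.54e-05, 0.32) and pro-apoptotic miRNAs (-0.24, 0.000755, 0.39). The rest were T-ALL oncogenic (-1.31, 0.00171, 0.32), T cell (-0.29, 0.00127, 0.381) and DNA damage response miRNAs (-0.22, 0.00558, 0.492). Without JAP replicate 1, camera no longer called let-7 (median -0.269, adjusted p = 0.0864), miR-15/16 (-0.143, 0.053) or DNA damage response miRNAs (-0.1, 0.112), and 6 lists passed in place of 9. Adjusted over the list alone, the 7 lists held 0, 2, 5, 5, 3, 3 and 5 lower members in the order given, which can again include entries near background. Of the 28 GC-rich entries 2 rose, and adjusted over the list alone 8 were higher and 3 lower (median 0.35, camera adjusted p = 5.63e-05, 0.32 estimated), with the direction turned down in the deposited matrix and the call lost without scaling (median 0.135, adjusted p = 0.0875) and with 75th-percentile scaling (0.277, 0.185). Without JAP replicates 1 and 2, the let-7 direction turned up (median 0.184).

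Treated cells that had not entered apoptosis were compared with untreated cells of the same sort fraction (JAN against JNN), which asks what camptothecin changed in cells that stayed non-apoptotic. None of the 866 entries passed limma's threshold, with 13 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. miR-17 stood at -0.15 (SE 0.24), miR-16 at -0.06 (SE 0.52), let-7a at 0.24 (SE 0.31) and miR-181a at 0.54 (SE 0.43). These SEs and p-values pool the spread of all 8 arrays, and the JAP arrays widen them, whereas the same pooling can narrow those of the comparisons with JAP. For let-7a the SD was 0.08 in JAN and 0.06 in JNN, but 0.73 in JAP. The smallest p-values belonged to miR-450a, miR-34c-5p, miR-1254, miR-520d-3p, miR-525-5p, miR-518c*, miR-507, miR-1257, miR-574-5p and miR-149. Of these 10, miR-1254 alone was above background on any JAN or JNN array, and it stood at -0.89 (SE 0.31). With only the JAN and JNN groups in the fit, 0 entries passed and 31 had an unadjusted p under 0.05 (limma).

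With no single member past the threshold, also when adjusted over the list alone (0 in each), camera called 4 lists higher in JAN than in JNN. All 4 calls were lost with the replicate number as a block, though the numbers of the mixed JNN samples need not match those of JAN. All 9 let-7 members had positive values (median 0.28, camera adjusted p = 0.00435, 0.5 with an estimated correlation), let-7d the largest at 0.54 (SE 0.40). All 4 miR-181 members were positive (median 0.30, camera adjusted p = 0.0268, 0.492 estimated). They are also members of the T cell list, so its call below is not independent of this one. The other 2 were T cell and haematopoietic miRNAs, 14 of 17 positive (median 0.22, adjusted p = 0.00558, 0.381 estimated), and hypoxia and stress miRNAs, 9 of 10 positive (median 0.17, adjusted p = 0.00435, 0.381 estimated). In the former, miR-128 was above background on 1 JAN array and no JNN array (at least 1.16-fold higher in JAN, not passing). In the latter, miR-23a and miR-24 were above background on no array of either group. Each of the 4 calls was also lost without some single array: let-7 without JAN replicate 1 or JNN replicate 2 (camera adjusted p = 0.0612 and 0.187), miR-181 without JAN replicate 1, JAN replicate 3 or JNN replicate 1 (0.0896, 0.231 and 0.244), T cell miRNAs without JNN replicate 1 (0.148), and hypoxia miRNAs without JAN replicate 3 or JNN replicate 2 (0.0802 and 0.0644). The miR-17~92 list had a median of -0.15 (camera adjusted p = 0.589).

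The changes against JNN in the apoptotic and the non-apoptotic treated fractions were set side by side. Across the 866 entries, which are not independent replicates, Pearson's r of the log2 fold changes was 0.12. Simulated unchanged groups that share simulated JNN arrays gave 0.60 ± 0.03 (SD, 1000 draws). All 8 arrays were drawn with 1 pooled SD per entry and were not normalized. That SD includes the JAP spread (for miR-17, 0.50 in JAP against 0.05 in JNN). The simulated r and covariance can therefore be too high, and no conclusion is drawn from the gap. The covariance was 0.0068 against a simulated 0.0211. Entries with the same sign made up 57.97%, against 70.5% simulated. No call was shared, and independent lists of 3 and 0 calls share 0. The shared JNN arrays alone raise r in such a comparison, and with 2 of them the controls could not be split.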

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

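Joint removal of JAP replicates 1 and 2, the filter on 2 arrays above background, and the overlap with single arrays left out were chosen after seeing the data. A fit without a filter on dim entries is the one reported, so it gives no separate value. The cause was not tested for any change below. Low signal limits these results: 727 of 866 entries were above background on no array.

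For JAP against JNN limma's 3 calls became 1 without background correction, 0 with cyclic loess, 13 (1 higher, 12 lower) with 75th-percentile scaling, 0 without scaling, 1 with the mean of spots and 0 with the deposited matrix. They became 6 with trend and robust settings (1 higher, 5 lower), 33 with array weights (8 higher, 25 lower), 22 at an adjusted p under 0.1 and 0 without JAP replicates 1 and 2. At an unadjusted p under 0.05 these counts of 0 had 78 entries with cyclic loess, 42 without scaling, 9 with the matrix and 41 without those replicates. Leaving out 1 array gave 0 to 85. For JAN against JNN the 0 calls became 1 with the deposited matrix (9 at an unadjusted p under 0.05), and stayed at 0 under all other settings, each array left out included.

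For JAP against JAN the 20 calls (6 higher, 14 lower) became 7 without background correction (6 higher, 1 lower), 12 with an offset of 16 (6 each way), 9 with cyclic loess (4 higher, 5 lower), 46 with 75th-percentile scaling (23 each way), 33 without scaling (0 higher), 13 with the mean of spots (7 higher, 6 lower) and 2 with the deposited matrix (0 higher). They became 12 among entries brighter than the median entry (6 each way), 38 with trend and robust settings (4 higher), 66 with array weights, 8 with only those groups in the fit (5 higher, 3 lower), 59 at an adjusted p under 0.1, 13 with at least a 2-fold change and 0 without JAP replicates 1 and 2 (49 at an unadjusted p under 0.05, limma). Leaving out 1 array gave 0 to 114. With the 2-array filter there were 30 calls, 18 of them among the 20. The 21 called values of named entries in both comparisons kept their sign, but each call was lost in 3 to 9 of 13 or 14 settings (9 for miR-182, miR-320b and miR-425) and kept in only 1 to 6 of 8 fits with 1 array left out. Values moved several-fold, as for miR-191 (-4.103 to -0.5503) and miR-130b (-5.135 to -0.7911).

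Whether replicate numbers pair samples is open, as most entries lie near background. JAP and JAN deviations correlated at 0.0163, 0.15 and 0.06 for equal numbers, -0.167 to 0.0656 for others. With the replicate number as a block there were 44, 0 and 72 calls for JAP against JNN, JAN against JNN and JAP against JAN, and 1 list for JAN against JNN in place of 4: all 4 higher lists lost their call (adjusted p = 0.0802 to 0.345), and miR-17~92 was called lower instead.

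Lists past camera's threshold numbered 9, 4 and 13 in the same order. With an estimated correlation they were 0, 0 and 0 (4, 0 and 4 at an unadjusted p under 0.05). For JAN against JNN they were 11 with 75th-percentile scaling, 8 without scaling and 11 with the deposited matrix, and 2 to 4 with 1 array left out. That range was 6 to 11 for JAP against JNN (6 without JAP replicate 1) and 11 to 13 for JAP against JAN. For JAP against JAN the hypoxia call was lost with array weights (adjusted p = 0.0681), with 75th-percentile scaling (0.129) and without JAP replicate 2 (0.0608) or JAN replicate 3 (0.0863), and the C19MC call without background correction (0.242) and without JAP replicate 1 (0.183) or JAN replicate 1 (0.0845). For JAP against JNN the miR-15/16 call was lost without background correction (0.147) and without JNN replicate 2 (0.052). For JAN against JNN hypoxia lost its call without background correction (0.0641) and miR-181 with the deposited matrix (0.156). The 2-array filter gave 4 for JAP against JNN and 7 for JAP against JAN, and removal of JAP replicates 1 and 2 gave 6 for JAP against JAN.

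Scaling to the 75th percentile moved the median of all entries to 0.205 (JAP against JNN), -0.417 (JAN against JNN) and 0.643 (JAP against JAN). Camera ranks a list against that shift, so its direction can oppose the list's median. The GC-rich list turned down for JAP against JAN with this scaling (median 0.623, adjusted p = 0.467), without scaling (0.0392, 0.66) and with the deposited matrix (-0.0964, 0.0836), and for JAP against JNN with the deposited matrix (0, 0.0915). The let-7 list turned up for JAP against JNN without JAP replicates 1 and 2 (0.184, 0.0415). For JAN against JNN, lists not called with quantile normalization were called with the opposite direction, up. They were miR-17~92 (-0.13 with 75th-percentile scaling, 0.312 without scaling, 0.305 with the deposited matrix), GC-rich entries (-0.267, 0.174 and 0.286) and T-ALL oncogenic miRNAs (-0.0969 with 75th-percentile scaling).

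The correlation of 0.119 between the comparisons with JNN was -0.0528 without background correction, 0.173 with an offset of 16, 0.0533 with cyclic loess, -0.16 with 75th-percentile scaling and without scaling, -0.0518 with the mean of spots, -0.14 with the deposited matrix and -0.0274 among entries brighter than the median entry. It ran from 0.0462 to 0.298 with 1 array left out.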

Other observations

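The tests weighed here were chosen after the results had been seen, except the count over other splits of the samples.

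The miR-320 members had the 4 lowest values on the GC-rich list between JAP and JAN, though no test set the family against the rest. The deposited intensity of miR-320a was 310 and 613 on JAP replicates 1 and 2, 2099 on JAP replicate 3 and 2848 to 3089 on the JAN arrays. Between JAP and JAN, miR-320a fell by 0.72 on the log2 scale (SE 0.14, adjusted p = 0.0266, limma) and miR-320b by 0.89 (SE 0.19, adjusted p = 0.0453). miR-320c stood at -0.74 (SE 0.28, adjusted p = 0.18) and miR-320d at -0.97 (SE 0.26, adjusted p = 0.0786). The first pair are the 2 entries of the GC-rich list that fell. That list was set by entry name, so its label need not hold for each member. miR-320a, miR-320c and miR-320d lie outside the naming rule and were chosen after their values were seen.

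The tRNA fragment entry miR-1308 had a deposited intensity of 15537 on JAP replicate 3, against 974 and 4254 on the other JAP arrays, 4696 to 5283 on JAN, and 2430 and 3523 on JNN.

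A contrast within each array was built from the lists with the smallest camera p upward and downward, which were also the extremes with JAP replicate 3 left out. The contrast is the median deviation of 20 GC-rich entries from their mean over the JAN and JNN arrays, minus that of 11 miR-17~92 members. It does not change with a shift per array of the log2 values. A factor on the intensities before the offset of 50 moves dim entries less than bright ones and can change it. It was 2.28, 1.82 and 0.901 on JAP replicates 1, 2 and 3 without scaling, and between -0.0997 and 0.0237 on the 5 JAN and JNN arrays. Since the lists were chosen for this difference, a test over all JAP arrays would be circular, and only JAP replicate 3 can be left out of the choice. With quantile normalization the JAP values were 2.95, 2.3 and 0.705. A ratio within an array shows unequal change, not which group of entries moved. One hypothesis is that a loss of miR-17~92 signal relative to GC-rich entries goes with the apoptotic fraction and differs in degree between sorts, but chip position is confounded with the group and no independent sample tests it.

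The first pattern weighed is that miRNA families were lower on JAP replicates 1 and 2 than on JAP replicate 3, where the miR-17~92 median without scaling was still -0.488 (-0.233 to 0.306 on JAN and JNN arrays). Dimness of an array, or a chip gradient, that acts on all entries alike is argued against by the size of a gap within each array. Without scaling, 22 family members had a median of -2.63 on JAP replicate 1 and 20 GC-rich and fragment entries -0.43, a gap of 2.2. The gap was 1.71 on JAP replicate 2 and 0.46 on JAP replicate 3. Permutation p-values over entries were 1e-05, 1e-05 (the smallest 100000 resamples can give) and 0.00272. These lists were set against each other after their changes on JAP replicates 1 and 2 had been seen, and entries of 1 array are not independent. Permutation p-values here and below therefore measure neither chance nor the spread between samples. JAP replicate 3 correlated at 0.9487 to 0.9699 with the JAN and JNN arrays and at 0.8851 and 0.9231 with the other JAP arrays, and its let-7 minus miR-17~92 difference (0.625) lay inside their interval (-1.02 to 0.976), but a wholly mislabelled JAN or JNN sample in its place is argued against by the contrast of 0.901 above, which lies outside the 95% prediction interval of the 5 other arrays (-0.183 to 0.153) as it did with quantile normalization (0.705) and cyclic loess (0.741). Lower recovery of all miRNAs by 1 common factor cannot be told apart from a loss that differs between miRNAs. From the deposited zero, 7 let-7 members were lower by less than the miR-17~92 members (4 on JAP replicate 1, 5 on JAP replicate 2). The differences were 1.351 on JAP replicate 1 and 1.174 on JAP replicate 2 (permutation p = 0.0121 and 0.0253, upper bound of the 5 other arrays 1.15). With zero at the median dim entry and 8 miR-17~92 members they were 1.088 and 0.937 (permutation p = 0.00311 for each, bound 1.07). JAP replicate 2 thus passed the bound with 1 zero only, and several members lay near background. On the offset log2 values without scaling, over 9 let-7 and 11 miR-17~92 members, the differences were only 0.149 and 0.119, inside the interval of -1.02 to 0.976. A loss in the sorted cells, uneven purity of the sort (non-apoptotic cells in JAP replicate 3) and recovery that depends on the sequence stay open. An effect of chip position that differs between entries also stays open. JAP replicates 1, 2 and 3 lie in that order on the chip (columns 1 to 28, 29 to 56 and 57 to 84). Such an effect could give the gap, and also the contrast of 0.901 in a mislabelled sample. These causes may act together, and none was tested.

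The second pattern is that GC-rich entries were higher on JAP than on JAN arrays. Quantile normalization could raise bright entries where miRNA families are lost: without scaling the median of 17 GC-rich entries above background on all 5 JAN and JNN arrays was -0.08622 in place of 0.70. This cannot be told apart from a real rise, because the members go both ways: without scaling the median against JAN was -0.4987 on JAP replicate 1 (0 of 17 above all JAN arrays), -0.1374 on JAP replicate 2 (8 of 17) and 0.3374 on JAP replicate 3 (10 of 17), with 75th-percentile scaling it was 0.7417, 0.2981 and 0.413 (13, 12 and 12 of 17), where the median of all entries also shifted by 0.643, and the 6 entries called for rising lay at 0.88 to 1.53 with quantile normalization and at 0.38 to 0.71 without scaling (limma adjusted p = 0.32 to 0.994). More ribosomal RNA fragments in the JAP samples is also open, although neither ribosomal entry had a positive value. miR-923 stood at -0.2409 (SE 0.12) and miR-1826 at -0.08 (SE 0.12) with quantile normalization, below the GC-rich median, but without scaling miR-923 stood at -0.02 (SE 0.28) and miR-1826 at -0.57 (SE 0.27), where the GC-rich median itself was -0.09, and the brightest entries hold nearly fixed ranks.

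The count of 20 entries between JAP and JAN was set against other splits of the same 6 arrays. Of the 10 splits into 3 against 3, 1, the real one, gave as many, and the highest other gave 0. With 10 splits no share under 0.05 can be reached.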
